A study of Rattus norvegicus with 5 samples.

How the data were processed

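The 5 samples are total RNA of primary rat hepatic stellate cells, converted to biotin-labelled cRNA and hybridised to Illumina bead arrays of 1 chip, per the labels. Per the submitters' processing notes GenomeStudio 2011.1 was used. The deposited non-normalized table gives, per the file headers, the mean bead intensity of each probe and array, the standard error of the bead intensities, the number of beads and a detection p-value. The deposited detection p-value sets a probe's signal against the negative control beads. The deposited intensities are all above 0 and differ in median between arrays, so no background subtraction or scaling is visible in them. The value table of the series holds intensities on a linear scale, as set against the deposited signals of each array: ranks within an array are those of the signal (Spearman rho 1), the sorted values of the arrays differ by at most 0.664% from their mean, and column medians lie between 115.7 and 115.9. Its values are thus those of a quantile normalization without background subtraction or centring, a step read from the values and named in no label. An aligner or genome build does not apply to the array values, and the probes' build is not given in the sources used here.

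From the deposited intensities, background was corrected with limma's neqc (limma 3.58.1 in R 4.3.3), which fits a normal-exponential model with negative controls inferred from the detection p-values, adds an offset of 16, applies quantile normalization over the 5 arrays and takes log2. This lifts and compresses dim signals, so that fold changes of dim probes are understated. Probes detected (detection p under 0.01) on at least 1 of the 5 arrays were kept, which left 9737 of 22523.

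Probe names came from the platform annotation. It gives 1 gene symbol for 13793 probes and several for 0, and it leaves 8730 unnamed here. Of its gene identifiers 99.7% were found in a RefSeq table of assembly GRCr8, used for names only, and 0 symbols had changed. The kept probes comprise 7183 named ones, of 7051 genes, and 2554 unnamed ones. A gene with several kept probes (126 genes) was represented by the probe of highest mean, and among such genes calls disagreed for Ier5, Slc25a30 and St8sia4.

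Groups were taken from the labels. A linear model with 1 mean per group was fitted to all 5 arrays with limma (lmFit and eBayes), so that the groups share an estimate of the spread with 2 residual degrees of freedom and a prior worth 3.65. The contrasts were calcitriol against vehicle, vehicle against the array labelled freshly isolated, and calcitriol against that array. Adjusted p-values are from limma's two-sided moderated test after Benjamini-Hochberg adjustment over the 9737 probes, with a threshold of 0.05. Standard errors are moderated ones. All 5 arrays were on the same chip, with no other batch in the labels or headers. The positions on the chip were A and B for vehicle, C and D for calcitriol and L for the array labelled freshly isolated. An effect of position therefore cannot be told apart from one of group.

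For 19 gene lists fixed before the data were examined, limma's camera (preset correlation of 0.01, Benjamini-Hochberg over the 19 lists) tested the shift of a list against all other genes, with 1 probe per gene. The lists cover vitamin D response, extracellular matrix, contractile genes, TGF-beta and SMAD signalling, matrix proteases, quiescence and retinoid storage, chemokines and inflammation, cell cycle, immediate early genes, antioxidant and unfolded protein response, interferon response, cholesterol and fatty acid synthesis, and glycolysis and hypoxia. They also cover markers of hepatocytes, macrophages, sinusoidal endothelium, biliary epithelium, lymphocytes, and mesothelial and portal fibroblast cells. With an estimated correlation none of the camera calls held. That form of the test rests on the 2 residual degrees of freedom, so it could hardly pass here. For the quiescent list with vehicle, camera's unadjusted p rose from 0.000502 to 0.0593, although the estimated correlation of -0.0113 lay under the preset one. For that list the lost call therefore does not show that correlation between genes made the shift. The estimated correlation lay above the preset one for the endothelial (0.0371), chemokine (0.0251) and cell cycle (0.0516) lists. For their calls a part of such correlation is not set aside.

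Genes named in the text were chosen by a rule also fixed before the data were examined. It takes the 12 largest rises and falls past the threshold in each of the first 2 contrasts (with calcitriol, only where both treated arrays lie beyond both vehicle arrays), the 5 largest in each direction for calcitriol against the array labelled freshly isolated, up to 4 members of each list with the smallest p, and Cyp24a1, Vdr, Col1a1, Col1a2, Col3a1, Acta2, Timp1, Tgfb1 and Lrat where measured.

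The relation of the changes across probes was set against 100 simulations in which unchanged calcitriol arrays were drawn around the vehicle means. The fit was also tested on simulated data with 9737 probes, of which 200 were changed. For calcitriol against vehicle it recovered 89.4% of changes of 4-fold, 17.9% of 2-fold and 2.99% of 1.5-fold, with 1 false call among 74. For vehicle against the lone array it recovered 84.8%, 2.99% and 1.49%, with 6 false calls among 65. For calcitriol against vehicle, camera called 100 of 100 simulated lists of 30 genes shifted by 0.5 and 1 of 100 unshifted ones at an unadjusted p under 0.05. The simulated genes were independent of each other, so false calls for lists of correlated genes were not tested.

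Alternatives were no background correction, an offset of 50, scaling to the array median, the value table of the series, other detection filters, the mean of a gene's probes, a variance trend with robust eBayes, a minimum fold of 1.2, other thresholds, leaving out each cultured array, the replicate number as a block, the cultured arrays alone, for the relation of changes and the distances between arrays a median scaling of the uncorrected log2 signal, and for lists an estimated correlation. The rotation test fry was also run for lists, and tests a list against no change rather than against other genes.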

Results

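Gene expression was measured in primary hepatic stellate cells of male Wistar rats, the vitamin A storing cells of the liver that turn into matrix-producing myofibroblasts when the liver is injured or when they are cultured on plastic. Total RNA was labelled and hybridised to 5 Illumina rat expression arrays. Of these, 1 array carries the label of freshly isolated, untreated cells, 2 hold cells at day 3 given vehicle, and 2 hold cells at day 3 given calcitriol at 100 nM for 24 h. Calcitriol is 1,25-dihydroxyvitamin D3, the hormonal form of vitamin D and the ligand of the vitamin D receptor. The stated purpose was to learn how vitamin D ligands affect the activated state of these cells. The labels do not say that replicates were separate cultures or animals, so limma's p-values for probes measure only the spread between these arrays, which may be technical. The p-values of limma's camera with the preset correlation compare genes with other genes. They do not measure how a list varies between arrays. The array labelled freshly isolated has no replicate, and the fit assumes that it varied like the cultured ones.

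The arrays were similar in median signal but not in mean signal. The mean ran from 608.2 on vehicle array 2 to 854.8 on the array labelled freshly isolated. The median probe signal lay between 110.3 and 121.3 intensity units, a probe's mean rested on a median of 40 or 41 beads, and the median standard error of that mean was 4.55% to 4.87% of the signal among the 9737 probes kept. Between 8316 and 9112 of 22523 probes were detected on an array. The signal at the 95th percentile of probes was 25.8 times the background on vehicle array 2, the dimmest, and 32.9 to 37.4 times on the other arrays. The number of arrays limits the precision.

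The main comparison asked what calcitriol changed in the day 3 cells, with 2 arrays per group. Cyp24a1, the enzyme that inactivates calcitriol and a direct target of the vitamin D receptor, was detected on both calcitriol arrays and on neither vehicle array, and was at least 6.71-fold higher with calcitriol (adjusted p = 0.00153). Nlrp3, an inflammasome sensor, rose 8.21-fold (log2 change 3.04 ± 0.16, SE, n = 2 per group), and the acid phosphatase gene Acp3 rose 7.13-fold (2.83 ± 0.14). In the other direction, Ch25h, whose enzyme makes an oxysterol, was 14.6-fold lower (log2 change -3.87 ± 0.33, adjusted p = 0.00845). Plau, the urokinase plasminogen activator, was 4.05-fold lower (-2.02 ± 0.13), and the cholesterol exporter Abcg1 was 3.08-fold lower (-1.62 ± 0.13). In total 114 probes were higher and 64 lower with calcitriol at an adjusted p under 0.05, which are 86 and 49 named genes, with 40 of the probes unnamed here.

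Where a probe was detected on no array of its dim group, the fold is given as a lower bound, the mean of the bright group against the lowest detected level of each dim array or the probe's own value if higher. By this rule Cela2a, a pancreatic elastase gene, was at least 8.42-fold higher with calcitriol, the neuropeptide gene Nmu at least 4.98-fold, Mpzl2 at least 3.82-fold, Hoga1 at least 3.16-fold and Jdp2, a member of the AP-1 family, at least 2.76-fold. Among genes detected in both groups, Amigo2 rose 7.10-fold, Rhpn1 4.61-fold and the small GTPase gene Gem 4.53-fold. Fbxo2 rose 4.02-fold and was detected on 1 of the 2 vehicle arrays. The other large falls were Chst1, a carbohydrate sulfotransferase (4.78-fold), the proton pump subunit gene Atp6v0a1 (3.37-fold), the chemokine receptor Cxcr4 (3.36-fold), Id2 (2.97-fold), Tmed5 (2.89-fold), the lectin receptor Clec4a1 (2.82-fold) and the phosphatase Ptpre (2.77-fold). B3gnt7 was at least 2.83-fold and Flrt3 at least 1.53-fold lower. Adjusted p for these genes ran from 0.000619 for Cela2a to 0.0376 for Fbxo2.

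**Figure D1:**
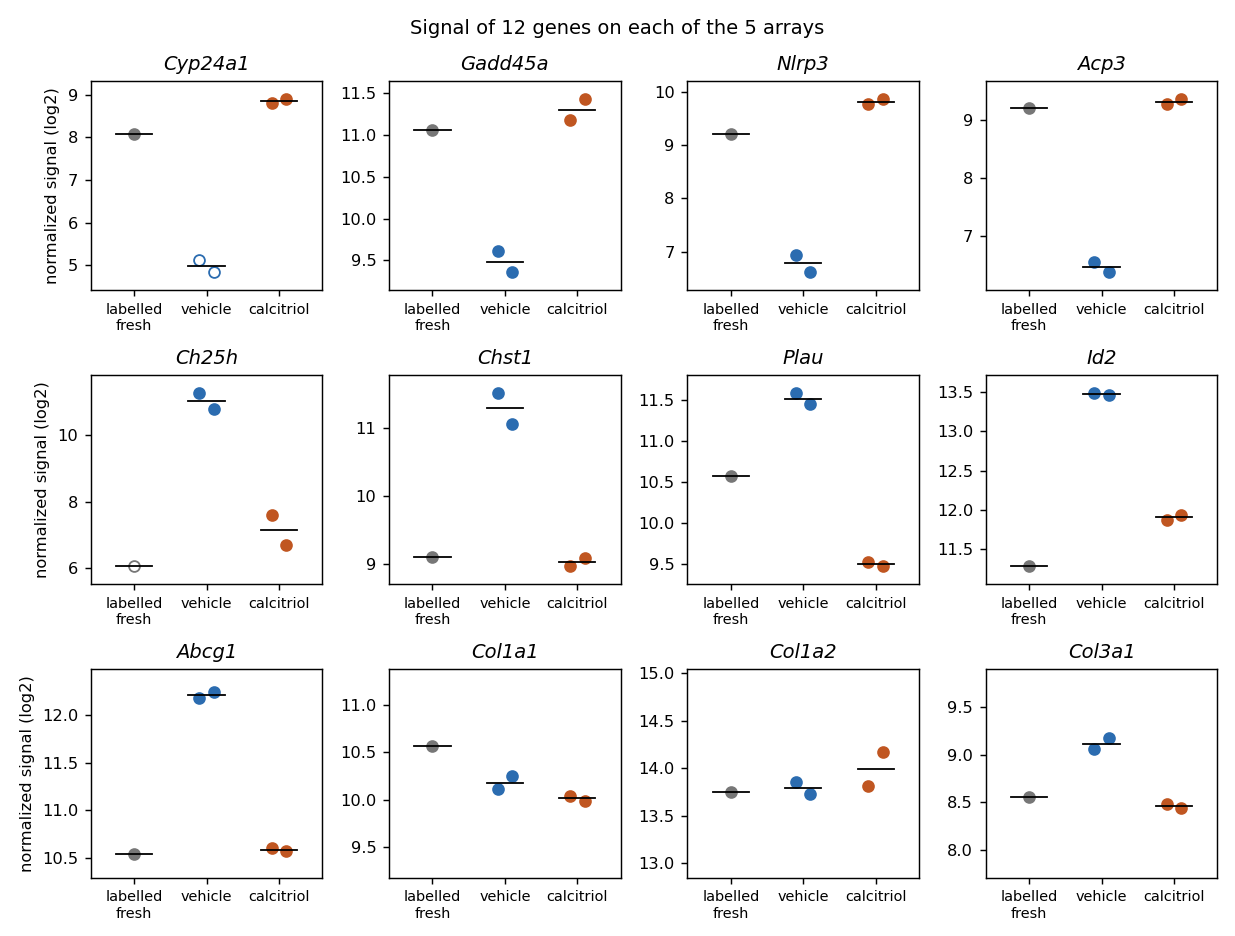
Normalized log2 signal (y axis) of 12 genes on each array, by group (x axis), where points are arrays, open points belong to groups in which the probe was detected on no array, and bars are group means. Cyp24a1 lies at a mean of 4.98 with vehicle, 8.85 with calcitriol and 8.09 on the array labelled freshly isolated, while Col1a1 and Col1a2 differ little between vehicle and calcitriol.

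Of 24 measured genes in the vitamin D response list, 2 rose and none fell (4 higher and 2 lower adjusted over the list alone). These were Cyp24a1 and Gadd45a, a growth arrest gene that was 3.52-fold higher (adjusted p = 0.0101). The receptor gene Vdr itself was at least 1.31-fold higher and missed the threshold (adjusted p = 0.0676), as did the growth factor gene Hbegf at 1.87-fold (adjusted p = 0.0666). In the chemokine and inflammatory list 4 of 40 genes rose and none fell (7 higher adjusted over the list alone). They were the cytokine Il1a at 3.78-fold, the adhesion molecule Vcam1 at 2.40-fold, the granulocyte growth factor Csf3 at 2.24-fold and the receptor Tlr2 at 1.86-fold. Outside that list Nlrp3 rose, as given above, while the chemokine Ccl12 fell 2.15-fold (adjusted p = 0.0414 in limma) and the nucleic acid sensor Tlr7 fell 2.37-fold (adjusted p = 0.0375).

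Of the lists of the myofibroblast state below none passed, and of their genes only Id2 and Plau did. In simulated data this comparison recovered 2.99% of 1.5-fold and 17.9% of 2-fold changes. The counts therefore do not show that single genes were without changes of that size. In the fibrillar collagen and extracellular matrix list 0 of 37 genes passed in limma, and 0 also adjusted over the list alone. Col1a1 had a log2 change of -0.17 ± 0.13 (adjusted p = 0.588, and 0.04 with scaling to the array median, which put the median change of the kept probes at 0.167), Col1a2 of 0.20 ± 0.17 (adjusted p = 0.62) and Col3a1 of -0.65 ± 0.13 (adjusted p = 0.0883). Of the 30 contractile genes 0 passed by either adjustment, with Csrp1 at 0.58 ± 0.13 and Flna at -0.34 ± 0.13. In the TGF-beta and SMAD list 1 of 33 genes passed by either adjustment, the transcriptional inhibitor Id2, which fell, and Tgfb1 had a log2 change of -0.31 ± 0.15 (adjusted p = 0.374). Among 29 matrix proteases and inhibitors only Plau passed, by either adjustment, and Timp1 had a log2 change of 0.15 ± 0.13. Acta2, the smooth muscle actin gene, and Lrat, the retinol esterifying enzyme, match none of the probe names used here and were not analysed.

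In the quiescent stellate cell and retinoid storage list 2 of 28 genes fell and none rose (6 lower and 1 higher adjusted over the list alone). These were Dgat2, which makes triglyceride (2.09-fold), and Srebf1, a regulator of fatty acid synthesis (1.98-fold). In the cholesterol and fatty acid list 3 of 27 fell and none rose, with the same count adjusted over the list alone, namely Abcg1, Srebf1 and the desaturase Scd2 (1.97-fold). In the immediate early list 3 of 30 fell (4 lower and 2 higher adjusted over the list alone), which were the kinase Sgk1 at 2.12-fold, Klf6 at 2.02-fold and Ier5 at 1.81-fold, and the probes of Ier5 did not all pass. In the interferon list 1 of 27 genes, Oasl, rose 1.86-fold (also 1 adjusted over the list alone). Cell cycle (0 of 73), antioxidant and unfolded protein response (0 of 35) and glycolysis and hypoxia (0 of 29) had no gene past the threshold in limma, and none adjusted over the list alone.

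Markers of other liver cells were measured beside these groups. Macrophage markers were well represented, with 35 of 36 detected on all 5 arrays. Of these 36, the actin regulator Coro1a rose 2.54-fold and Ptprc, the pan-leukocyte surface phosphatase, fell 2.35-fold (1 higher and 4 lower adjusted over the list alone). Of 55 hepatocyte markers with a named probe only 12 were detected on any array, and 1 of them, the urea cycle gene Arg1, which macrophages also express, fell 2.08-fold (also 1 adjusted over the list alone). Among 14 lymphocyte markers Ptprcap was at least 2.67-fold higher (3 higher and 1 lower adjusted over the list alone). No gene passed in limma among 25 sinusoidal endothelial, 7 biliary or 13 mesothelial and portal fibroblast markers, of which adjusted over the list alone only 1, a mesothelial and portal fibroblast marker, was lower. Given the detected macrophage markers, the RNA may include that of macrophages. The changes with calcitriol therefore cannot be assigned to stellate cells alone from these arrays.

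With limma's camera, which compares a list's genes with all others, 0 of 19 lists passed. The lowest adjusted p values were 0.0703 for the chemokine list (median log2 change 0.09, or 0.05 with bounds for undetected probes and 0.28 with scaling to the array median), 0.0737 for the quiescent list (-0.08, and 0.05 with scaling to the array median) and 0.0904 for the hepatocyte list (-0.24, and -0.12 with scaling to the array median), each with an adjusted p = 0.664 with an estimated correlation. The median, mean and camera direction differed in sign for the protease list (0.02, -0.06, down), the cholesterol list (0.02, -0.09, down) and the mesothelial and portal fibroblast list (0.04, -0.03, up). At an unadjusted p under 0.05 limma counted 1541 probes, where 487 would come by chance. Without calcitriol array 1 or 2 no probe passed in limma (1355 and 875 at an unadjusted p under 0.05), and without vehicle array 1 or 2 there were 73 and 83, in fits with 1 residual degree of freedom. Among other settings the count ran from 100 with a minimum fold of 1.2 to 705 with a variance trend, the latter 350 higher and 355 lower. It was 237 higher and 61 lower with scaling to the array median, and 265 higher and 223 lower without background correction.

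**Figure D2:**
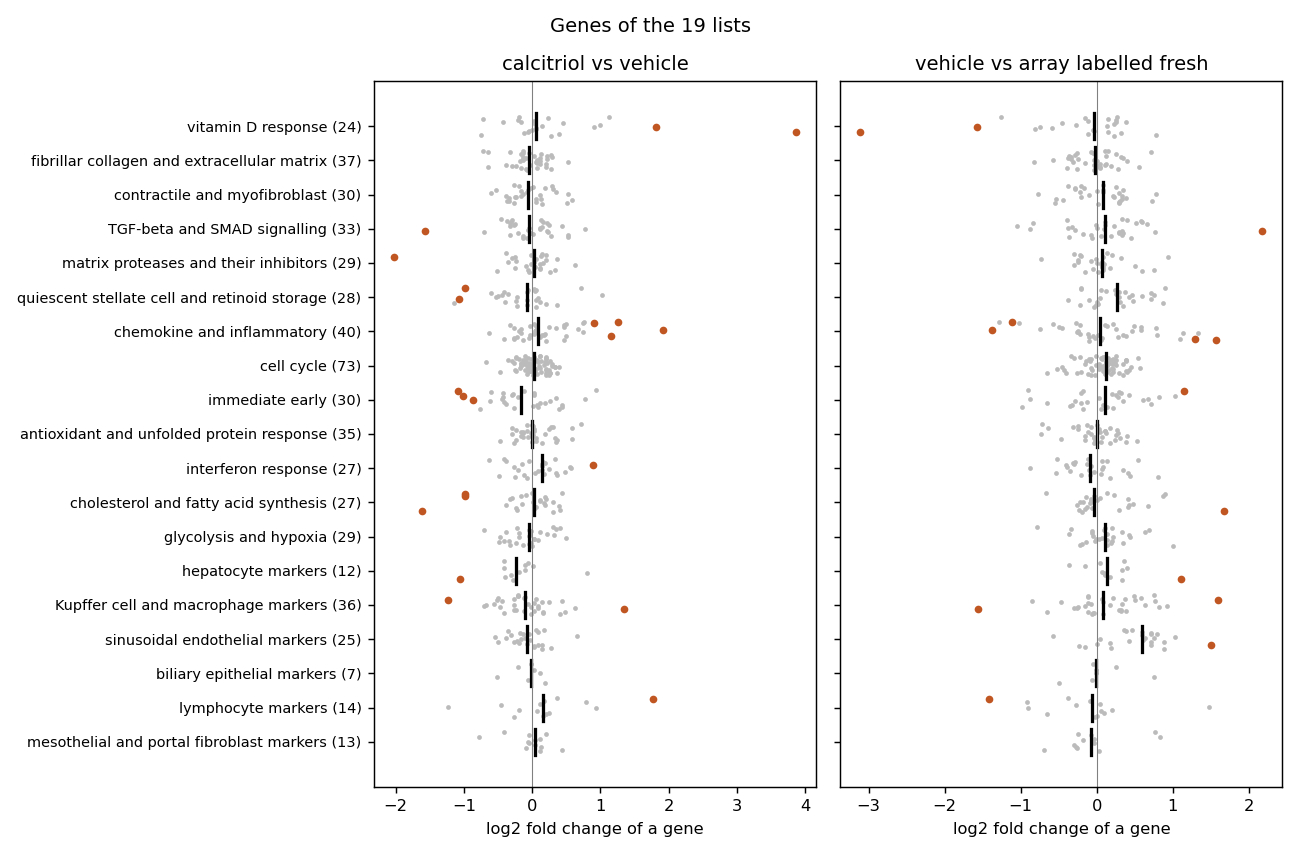
Log2 fold change (x axis) of each measured gene of the 19 lists (y axis, number of genes in brackets) with calcitriol against vehicle on the left and with vehicle against the array labelled freshly isolated on the right. Coloured points passed an adjusted p of 0.05 in limma, and bars are list medians, of which the sinusoidal endothelial one on the right is 0.60.

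The next comparison set the vehicle arrays at day 3 against the array labelled freshly isolated, which is the change with culture if that label holds. Ch25h was at least 29.1-fold higher with vehicle (adjusted p = 0.0147), and Id2 was 4.55-fold higher (log2 change 2.18 ± 0.15, SE, 2 arrays against 1). The chemokine Ccl12 was 4.48-fold higher (2.16 ± 0.20) and Cxcr4 was 3.94-fold higher (1.98 ± 0.16). Cyp24a1 was at least 3.94-fold lower with vehicle (adjusted p = 0.00991), so that it was detected on the array labelled freshly isolated, which by its label had no treatment, as well as on the calcitriol arrays. Acp3 was 6.62-fold lower (-2.73 ± 0.17) and Nlrp3 was 5.38-fold lower (-2.43 ± 0.20). In limma 47 probes were higher and 102 lower with vehicle, which are 28 and 77 named genes.

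Further genes higher with vehicle were Chst1 (4.56-fold), Atp6v0a1 (4.13-fold), Ptpre (3.40-fold), Abcg1 (3.18-fold), the nucleic acid sensor Tlr7 (3.17-fold), Exo5 (3.03-fold), Ptprc (3.01-fold) and Flrt3 (at least 1.37-fold). Further genes lower were Cela2a (at least 10.9-fold), Gem (6.04-fold), Amigo2 (5.32-fold), Rhpn1 (4.99-fold), Gprc5a (at least 3.56-fold), Hoga1 (at least 3.58-fold), Jdp2 (at least 3.30-fold) and Pacsin1 (at least 2.14-fold). Fbxo2 was 5.61-fold lower and was detected on 1 of the 2 vehicle arrays.

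Matrix and contractile genes, which define stellate cell activation, did not pass against the array labelled freshly isolated. For this comparison the fit recovered 2.99% of simulated 2-fold changes, so changes of single genes of that size could be missed. In limma 0 of 37 matrix and 0 of 30 contractile genes passed, also adjusted over the list alone, with median log2 changes of -0.02 and 0.08 (the latter -0.09 with scaling to the array median, which put the median change of the kept probes at -0.185). Col1a1 had a log2 change of -0.39 ± 0.16 (adjusted p = 0.372), Col1a2 of 0.04 ± 0.21, Col3a1 of 0.56 ± 0.16, Timp1 of -0.30 ± 0.16 and Tgfb1 of 0.11 ± 0.18, of which Col1a2 (-0.24) and Tgfb1 (-0.19) changed sign with that scaling. Id2 was the one of 33 TGF-beta and SMAD genes that passed (1 higher and 1 lower adjusted over the list alone), and no protease gene passed among 29 (1 higher adjusted over the list alone). The quiescent list was shifted upward with vehicle in camera (median 0.27, or 0.02 with scaling to the array median, adjusted p = 0.00476), with an adjusted p = 0.563 with an estimated correlation, although 0 of its 28 genes passed in limma or adjusted over the list alone. With that scaling, where the kept probes had a median of -0.185, the list still passed in camera. Its leading members were Srebf1 at a log2 change of 0.90 ± 0.17 and the lipid droplet protein gene Plin2 at 0.71 ± 0.16.

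Sinusoidal endothelial markers were shifted upward with vehicle (median 0.60, or 0.45 with bounds for undetected probes and 0.35 without background correction, adjusted p = 1.95e-06 in camera), with an adjusted p = 0.563 with an estimated correlation. Of 25 genes 22 had a higher value and 1 passed, the sialomucin Emcn, at least 2.14-fold higher (10 higher and 1 lower adjusted over the list alone). Among chemokine genes Ccl20 (2.96-fold) and Ccl3 (2.44-fold) were higher, and Il1a (2.61-fold) and Tlr4 (2.17-fold) were lower, of 40 (6 higher and 4 lower adjusted over the list alone). In the vitamin D list Cyp24a1 and Gadd45a (2.97-fold) were lower, of 24 (1 higher and 6 lower adjusted over the list alone). Sgk1 was 2.23-fold higher, alone of 30 immediate early genes (5 higher and 3 lower adjusted over the list alone), as was Abcg1 alone of 27 cholesterol genes (3 higher and 1 lower adjusted over the list alone).

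Among cell type markers Arg1 was 2.15-fold higher, 1 of 12 hepatocyte genes (also 1 adjusted over the list alone). Coro1a was 2.95-fold lower and Ptprc higher, of 36 macrophage genes (2 in each direction adjusted over the list alone). Ptprcap was at least 2.10-fold lower, of 14 lymphocyte genes (1 higher and 4 lower adjusted over the list alone). In limma 0 genes passed of the cell cycle, antioxidant, interferon and biliary lists, also adjusted over the list alone. None passed of the glycolysis and the mesothelial and portal fibroblast lists either, with 1 higher and 1 lower in each adjusted over the list alone. The median and mean differed in sign for the cholesterol list (-0.04 and 0.15) and the biliary list (-0.01 and 0.06), both up in camera without passing. Without calcitriol array 1 or 2, which enter this comparison only through the spread, no probe passed in limma (1155 at an unadjusted p under 0.05 each time), and without vehicle array 1 or 2 there were 60 and 57. Among other settings the counts ran from 90 with a minimum fold of 1.2 to 547 at an unadjusted p under 0.01 with 1.5-fold, and were 518 with a variance trend, 179 higher and 222 lower without background correction and 56 higher and 220 lower with scaling to the array median.

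The last comparison set the calcitriol arrays against the array labelled freshly isolated. Ccl20, a chemokine, had the largest higher value with calcitriol, 4.12-fold (log2 change 2.04 ± 0.23, 2 arrays against 1), and Sema7a the largest lower value, 3.66-fold (-1.87 ± 0.22). Both had an adjusted p = 0.213, the lowest of any probe, so that 0 probes passed in limma, with 649 at an unadjusted p under 0.05 where 487 would come by chance, but 435 with scaling to the array median and 468 without calcitriol array 2. The next values were Emcn at least 2.26-fold, Apln 2.80-fold, Hhip at least 1.92-fold and Prl8a9 at least 1.35-fold higher, and Spink8 2.94-fold, Duox2 2.72-fold (detected on 1 of 2 calcitriol arrays), Tsku at least 2.27-fold and Lcn12 at least 1.86-fold lower, none of which passed. The count was 30 without background correction, 22 with scaling to the array median, 56 with a variance trend and 198 at an unadjusted p under 0.01 with 1.5-fold.

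As lists, sinusoidal endothelial markers were shifted upward with calcitriol against the array labelled freshly isolated (median 0.46, or 0.29 with bounds, adjusted p = 7.22e-08 in camera), with an adjusted p = 0.555 with an estimated correlation. The chemokine list was shifted upward too (median 0.11, adjusted p = 2.32e-05), also with an adjusted p = 0.555 with an estimated correlation. The cell cycle list had a median of 0.12 (adjusted p = 0.018), with an adjusted p = 0.991 with an estimated correlation. In these lists 5 endothelial and 5 chemokine genes were higher adjusted over the list alone, and 0 over all probes in limma. The list tests of this comparison were not in the plan, and were not repeated under other scalings or with an array left out. The rotation test fry gave an adjusted p of 0.317 for the endothelial and chemokine lists and 0.747 for the cell cycle list.

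Across the 9737 probes the array labelled freshly isolated was about as near to the calcitriol arrays as replicates were to each other. Its root mean square log2 difference was 0.309 and 0.324 from the calcitriol arrays and 0.439 and 0.436 from the vehicle arrays, against 0.314 between the vehicle arrays and 0.285 between the calcitriol arrays. Between it and each calcitriol array 95 and 97 probes differed at least 2-fold, and between it and each vehicle array 346 and 312.

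A further question was whether genes changed with calcitriol in the direction opposite to vehicle against the array labelled freshly isolated, a difference that is a change with culture only if that label holds. Of the probes called both with calcitriol against vehicle and with vehicle against the array labelled freshly isolated, all 102 went in opposite directions. Of these, 77 were higher with calcitriol and lower with vehicle against the array labelled freshly isolated, including Cyp24a1, Nlrp3 and Acp3. The other 25 were lower with calcitriol, including Ch25h, Abcg1 and Id2. Both comparisons hold the same vehicle arrays, which alone gives opposite changes. Across probes, which are not independent replicates, the changes had r = -0.738, against -0.243 for simulated unchanged calcitriol arrays, and a covariance of -0.109 against -0.0224. With a different vehicle array in each comparison r was -0.415 and -0.576 and the covariance -0.0758 and -0.0939. Those comparisons share no array, and each rests on 1 vehicle array. The covariance with the shared arrays was -0.087 beyond the simulated one.

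**Figure D3:**
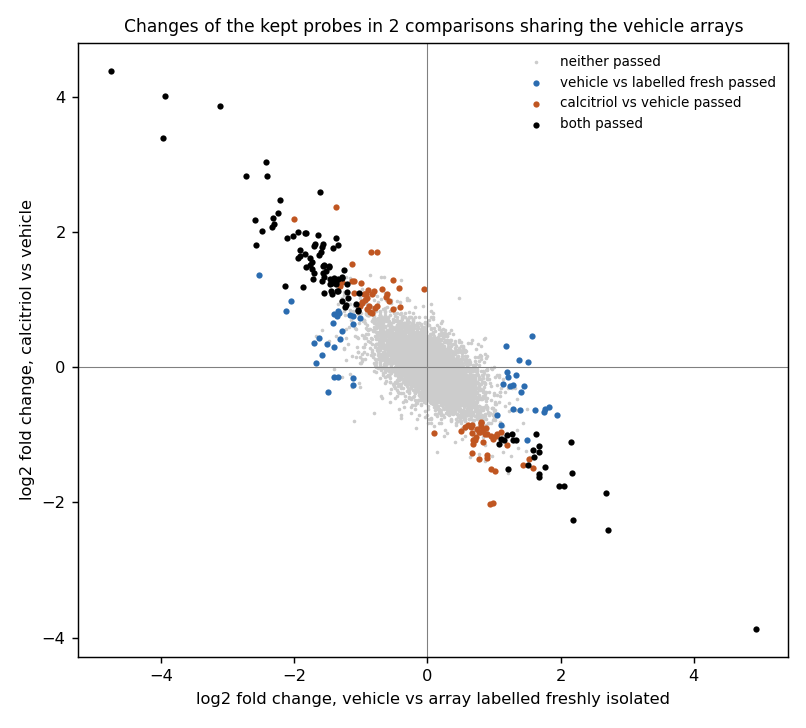
Log2 fold change of each of 9737 probes with vehicle against the array labelled freshly isolated (x axis) and with calcitriol against vehicle (y axis). The 102 probes that passed in both comparisons (black) lie to the upper left and lower right of the origin, and the vehicle arrays enter both axes.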

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

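The crossed pairing and the median scaling of uncorrected signals were chosen after seeing the data, and the cause of each difference was not tested unless stated. Without background correction 488 probes passed with calcitriol against vehicle, 401 with vehicle against the array labelled freshly isolated and 30 with calcitriol against it, and the value table of the series gave 488, 401 and 30. An offset of 50 gave 359 and 307, median scaling 298, 276 and 22, a variance trend 705, 518 and 56, a minimum fold of 1.2 gave 100 and 90, an adjusted p under 0.1 gave 342 and 283, and an unadjusted p under 0.01 with 1.5-fold gave 522, 547 and 198. Of the 178 probes called with calcitriol against vehicle, 173 to 178 were called again in the looser of these settings except median scaling, with 156. With 1 array left out, which leaves 1 residual degree of freedom, the counts ran from 0 to 83 with calcitriol against vehicle and from 0 to 60 with vehicle against the lone array. The other detection filters and the mean of a gene's probes stayed within 1.5 times.

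The replicate numbers do not pair the arrays by any label, and the differences between replicate 1 and 2 in the vehicle and calcitriol groups had r = -0.106 across probes. With the replicate block 129 probes passed, and with the crossed pairing 204. The 4 cultured arrays alone, normalized without the array labelled freshly isolated, gave 182, which include all 178.

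With calcitriol, the number of lists past camera's threshold was 0 and became 1 without background correction and with the value table of the series (chemokine), 2 with median scaling (chemokine and vitamin D), and 0 to 2 with 1 array left out. With vehicle against the lone array it was 2 and became 0 with an estimated correlation, a form that rests on 2 residual degrees of freedom. The rotation test fry, which tests a list against no change rather than against all other genes, gave an adjusted p of 0.0725 for both lists. The correlation of the changes, -0.738, became -0.415 and -0.576 with separate vehicle arrays and -0.243 for simulated unchanged arrays, was -0.772 with uncorrected signals scaled to the array median, and lay between -0.767 and -0.731 under the other scalings and filter.

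Of 1763 values of named genes under alternatives 1368 kept their direction and side of the threshold, 219 lost their call, 171 gained one and 5 changed sign, none of them a called gene. Leaving out either calcitriol array ended the calls of all 40 and 34 named genes of the first 2 contrasts, with unchanged direction. The block ended 7 of 40. Of 551 list values 33 medians changed sign, none of a list that had passed.

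Median scaling put the median change of the kept probes at 0.167 with calcitriol and at -0.185 with vehicle, so changes under it are relative to that shift. With calcitriol it gave Col1a1 0.04, macrophage 0.12, TGF-beta 0.11, biliary 0.16, contractile 0.09, matrix 0.17, glycolysis 0.14, immediate early 0.04, quiescent 0.05 and endothelial 0.01. With vehicle against the lone array it gave Col1a2 -0.24, Tgfb1 -0.19, macrophage -0.13, TGF-beta -0.07, cell cycle -0.10, chemokine -0.14, contractile -0.09, glycolysis -0.11, immediate early -0.10 and protease -0.16. A detection p under 0.05 gave the biliary list 0.01 with calcitriol and the vitamin D list 0.05 with vehicle, and no filter gave the latter 0.07.

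With 1 array left out, values ran from -0.11 to 0.05 for TGF-beta, -0.15 to 0.10 for biliary, -0.01 to 0.04 for cholesterol, -0.05 to 0.02 for matrix, -0.02 to 0.07 for protease and -0.01 to 0.17 for mesothelial genes with calcitriol. With vehicle against the lone array they ran from -0.02 to 0.11 for Col1a2, -0.17 to 0.07 for St14, -0.16 to 0.15 for biliary, -0.04 to 0.05 for cholesterol, -0.01 to 0.08 for contractile, -0.05 to 0.01 for matrix and -0.04 to 0.05 for vitamin D genes. The hepatocyte list passed with calcitriol only without calcitriol array 1 (adjusted p = 0.0219), and the lymphocyte list passed with vehicle only with detection on at least 2 arrays (adjusted p = 0.0417). The signal over background was lowest on vehicle array 2, at 25.8 for the 95th percentile, which limits what can be read for dim probes there.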

Other observations

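The slope, the distances under other scalings, the spreads and directions of marker lists and each test of an explanation in this part were chosen after the results were seen, while the limma calls and the list tests with an estimated correlation were planned.

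The array labelled freshly isolated lay with the calcitriol arrays, although by its label it had no treatment. Over the 178 probes called with calcitriol against vehicle, its difference from vehicle array 2 had a slope of 0.966 on the difference of the calcitriol mean from vehicle array 1, and 0.973 with the vehicle arrays exchanged, and 169 of these probes were nearer to the calcitriol mean than to the vehicle mean, as were 5794 of all 9737 probes kept (59.5%). Normalization is argued against as the source, since under 4 other scalings, among them median scaling of the log2 signal with neither background correction nor quantile normalization, the nearest vehicle array was at least 1.32 times as far as the farthest calcitriol array. A mislabelled sample, RNA of calcitriol-treated cultured cells under the fresh label, stays open as a candidate explanation, but the slope gives it no support, since it restates the pattern and a return of treated cells to the fresh state would give the same. Such a return has no support from the activation lists. Textbook activation would raise the matrix and contractile lists in culture, and neither rose with vehicle against that array. Acta2 of the contractile list and Lrat of the quiescent list had no named probe, so the values below lack them. The matrix list had a median of -0.02. The contractile list had 0.08 (0.02 with bounds for undetected probes). With median scaling it had -0.09, where the kept probes had a median of -0.185. Both lists had members in both directions. The quiescent list, which activation would lower, was instead higher with vehicle (median 0.27, or 0.24 with bounds and 0.02 with median scaling), although 0 of its 28 genes passed in limma. With 1 array, an assumed profile and RNA that may include that of macrophages, these values do not exclude a return, so it stays open too. The labels were kept as given.

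Of 36 macrophage markers, 4 were higher and 7 lower with calcitriol at an unadjusted p under 0.05 in limma, and the SD of the 36 log2 changes was 0.45, with a median standard error of 0.14.

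Of 25 sinusoidal endothelial markers 19 had lower values on the array labelled freshly isolated than in both cultured groups, and only Emcn passed, with vehicle (list adjusted p = 0.563 with vehicle and 0.555 with calcitriol with an estimated correlation). Dim probes and background correction are argued against, since the 18 markers detected on all arrays had a median of 0.43 with vehicle against that array without background correction, and 0.62 with it. A lower share of endothelial cells on that array may contribute: 14 of the 18 markers (77.8%) were higher in both cultured groups, but the SD of their changes was 0.42 against a median standard error of 0.18, so this cannot be told apart from changes of single genes with 1 array. A biological difference between fresh and cultured cells was not tested apart from these.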
